A study of Mus musculus with 10 samples.

How the data were processed

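Mouse livers carrying colorectal cancer metastases were profiled by 10x droplet single-cell RNA sequencing with T cell receptor V(D)J sequencing of the same cells. Per the labels' protocols, livers were digested with collagenase, Dispase II and DNase, no antibody was used, and viable single cells that excluded the dye 7AAD were sorted before loading. The labels name 3 groups in 5 livers: Control (livers 11 and 25), IFNa (livers 18 and 23) and IFNa with anti-CTLA-4 (liver 22, the combination). Sample numbers joined the gene expression and V(D)J libraries of 1 liver. The labels do not say whether each liver came from its own mouse, so p-values measure the spread between these samples, which may be partly technical.

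The deposited gene expression matrices hold raw UMI counts per gene and barcode, not normalised, which the authors made with Cell Ranger 7.0.1 on mm10, per the submitters' processing notes. The deposited V(D)J tables list contigs with their read and UMI counts per barcode, made with the same tool per the same notes. The 5 matrices share 32285 genes. Library totals ran from 10464216 to 69856071 UMIs. Control 25 had 863 cells against 5574 to 9605 in the others, so its shares carry the widest intervals.

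Barcodes with at least 200 genes and at most 15% mitochondrial UMIs were kept. Doublets were scored per library as the share of simulated doublets among each cell's nearest neighbours, and the top-scoring cells were removed up to 0.8% per 1000 cells, so the number removed was set by that expected rate. Removed doublets numbered 252 and 6 in Control 11 and 25, 310 and 246 in IFNa 18 and 23, and 728 in the combination, which left 26229 of 28039 cells. Counts were log-normalised to 10000 per cell, and 2500 variable genes were taken without interferon and MHC list genes, receptor segments, mitochondrial, ribosomal and haemoglobin genes and Xist. Then 40 principal components, 20 neighbours and Leiden clustering at resolution 2.0 gave 52 clusters (scanpy 1.11.5, Python 3.11.15).

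A cluster took the name of the marker list with the highest mean relative expression, called "X-like", where the score reached 0.45, at least 3 markers were detected and no other lineage came within 0.06. A T cell name also needed a T cell receptor beta chain in 30% of barcodes, and a cluster led by markers of another class, or of low UMI count with none of its own markers leading, stayed unnamed. The marker lists and gene lists were fixed before the data were examined. These thresholds were set afterwards and kept 5.46% and 2.49% of the cells of Control 11 and 25 out of every class, 7.29% and 10.5% of IFNa 18 and 23, and 34.4% of the combination. The median UMI count of the unnamed cells was 2069 and 2626 in Control, 1037 and 2203 in IFNa and 1528 in the combination. Cholangiocyte and colorectal cancer clusters were joined as epithelial-like cells, because the marker lists share keratin genes. T cell clusters were divided into 24 subclusters, named CD8, CD4, regulatory or gamma-delta by detection of the defining genes in at least 50% of cells and of the opposing gene in under 25%. No cluster was named Kupffer-like. The gene table lacks Mx1, Mx2, Cxcl11 and Lypd8l, which left those members of the fixed lists unmeasured.

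Cells were not treated as replicates. UMI counts were summed per library and class with at least 10 cells, filtered with filterByExpr, scaled with TMM and tested with edgeR 4.0.16 quasi-likelihood tests in 1 fit of all 3 groups, with Benjamini-Hochberg adjustment per class and a threshold of 0.05. Standard errors were taken as the absolute log2 fold change over the square root of the F statistic. The combination has 1 library, which is assumed to vary like the other groups. Cells per class were tested with the same model, with all kept cells as library size and no TMM. The 19 gene lists were tested with fry (limma 3.58.1), adjusted over all list and class pairs of a comparison. They cover type I interferon, interferon-gamma-inducible GTPases and chemokines, MHC class I and class II, inflammatory cytokines, alternatively activated macrophages, Kupffer cell identity, IL-10 signalling, T cell exhaustion, cytotoxic effectors, naive T cells, type 1 regulatory T cells, regulatory T cells, proliferation, dissociation stress, and transcripts of hepatocytes, neutrophils, erythroid cells and colorectal cancer epithelium. Differences of the IFNa effect between classes were tested as the interaction of class and group against CD8 T cell-like cells, with the library as a block.

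Named genes were chosen before the data were examined by a rule on size: per class, up to 10 genes each way for IFNa against Control and up to 5 each way for the combination, with adjusted p under 0.05, at least 20 CPM in the higher group and libraries on the same side, plus up to 4 members per list and a fixed set of macrophage and T cell genes. Trbv5 and Igkv4-59, outside that rule, were chosen after their values were seen. A clonotype was the V and J genes and nucleotide CDR3 of the TRA and TRB contigs of highest UMI count, and it counted as expanded with 2 or more barcodes. Clonality was also computed after thinning to the lowest number of paired barcodes, over 1000 draws. Shares carry exact (Clopper-Pearson) 95% intervals, which cover counting error only, as does the limit of 3 counts used for a count of 0. An exact permutation test of 2 against 2 libraries cannot reach 0.05, so clonality was given as values.

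The gene tests were tested on simulated counts with 200 changed genes, drawn among genes with a mean of at least 20 CPM. Every gene took the dispersion of the trend, in the lone combination library as well, so variation particular to single genes was left out. For IFNa against Control, edgeR recovered 95% of genes changed by 1 log2 unit in classical monocyte-like cells, 90% in B-like, 73% in macrophage-like, 33% in epithelial-like and 25% in CD8 T cell-like cells, and 97% to 100% of genes changed by 2 units except 93% in CD8. For the combination against Control it recovered 64%, 83%, 29%, 5% and 14% at 1 unit, and 100%, 100%, 84%, 51% and 87% at 2 units, in the same order. Alternatives covered DESeq2 1.42.0, RLE size factors, no filter on low counts, doublets kept, classes from a marker score per cell, at least 30 cells per class, each library left out, other denominators, a stricter cell filter, a finer clustering and other clonotype definitions. Coordinates come from GENCODE vM21 on GRCm38.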

Results

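Mice carried liver metastases of colorectal cancer and received a lentiviral vector. Control livers (11 and 25, n = 2) had a control vector, IFNa livers (18 and 23, n = 2) a vector for the type I interferon IFNa, and the combination liver (22, n = 1) the IFNa vector with an antibody against CTLA-4, an inhibitory receptor of T cells. The comparisons ask how interferon delivered through engineered liver macrophages, alone or with CTLA-4 blockade, alters the cells of the metastatic liver. The UMI totals were 55351421 and 10464216 in Control, 48124364 and 53608465 in IFNa and 69856071 in the combination, over 5707, 863, 6290, 5574 and 9605 cells. Median UMI counts per cell were 7868 and 9346 in Control, 5874.5 and 7686 in IFNa and 4983 in the combination. The T cell receptor libraries paired a TRA with a TRB chain in 684, 106, 683, 980 and 2925 barcodes.

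CD8 T cell-like cells made up 17.7% of the combination liver (exact 95% interval 16.9 to 18.5), against 4.76% and 3.67% in the Control livers and 4.58% and 7.59% in the IFNa livers. Plasma cell-like cells reached 1.84% there, against a Control mean of 0.324% (SD 0.379, n = 2) from 3 and 5 cells. Epithelial-like cells fell to 0.204% (18 cells) from a Control mean of 4.28%, and macrophage-like cells to 0.794% from 7.12%. The epithelial-like cells of Control and the combination all lay in cluster 7, whose highest-scoring list was cholangiocyte. Tumour cells and bile duct cells were not told apart in it. Classical monocyte-like cells fell from 27.5% to 6.97%, and neutrophil-like cells from 6.05% to 0.0340% (3 cells). All libraries came from viable 7AAD-negative sorts, and 34.4% of the combination cells lay in unnamed clusters.

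In the edgeR test of cells per class, 8 of 20 classes passed for the combination against Control, with the 1 combination library assumed to vary like the other groups. CD8 T cell-like cells rose by 2.05 ± 0.53 on the log2 scale (edgeR adjusted p = 0.0131) and plasma cell-like cells by 3.43 ± 1.20 (edgeR adjusted p = 0.0482). Epithelial-like cells fell by 4.35 ± 0.68 (edgeR adjusted p = 0.00151) and neutrophil-like cells by 7.38 ± 1.12 (edgeR adjusted p = 0.00151). Macrophage-like, classical monocyte-like, basophil-like and erythroid-like cells also fell. With classes from marker scores erythroid-like cells rose instead (log2 ratio 1.39, edgeR adjusted p = 0.0329). Leaving out Control 11 reduced the classes that passed to 5, adding hepatocyte-like cells (edgeR adjusted p = 0.0263) and ending the calls for plasma cell-like (edgeR adjusted p = 0.215), CD8 T cell-like (0.0656), classical monocyte-like (0.101) and erythroid-like cells (0.0789). Leaving out Control 25 ended CD8 (0.0909) and monocyte (0.0687), plasma failed without IFNa 18 (0.0559) or IFNa 23 (0.0560), and among cells neither T nor NK-like 3 classes passed.

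Against IFNa, the combination liver again held more CD8 T cell-like (log2 ratio 1.54 ± 0.52, edgeR adjusted p = 0.0444) and plasma cell-like cells (2.83 ± 0.97, edgeR adjusted p = 0.0444). It held fewer epithelial-like (-4.00 ± 0.67, edgeR adjusted p = 0.00476), macrophage-like, neutrophil-like, mature dendritic, basophil-like and erythroid-like cells, 8 classes in all with the 1 combination library assumed to vary like the others. With classes from marker scores erythroid-like cells rose instead (log2 ratio 1.30, edgeR adjusted p = 0.0398) and mature dendritic cells were at 0.26 (edgeR adjusted p = 0.729). With doublets kept 3 classes passed, and CD8 T cell-like (edgeR adjusted p = 0.0701), plasma cell-like (0.0987), neutrophil-like (0.0701), mature dendritic (0.192) and basophil-like cells (0.0827) did not. Between IFNa and Control no class passed in edgeR, with 2 below an unadjusted p of 0.05: neutrophil-like cells (1.91% against 6.05%, log2 ratio -1.67 ± 0.58, edgeR adjusted p = 0.190) and basophil-like cells (-1.54 ± 0.51, edgeR adjusted p = 0.190). CD8 T cell-like cells no longer passed against IFNa without Control 11 (edgeR adjusted p = 0.0807), Control 25 (0.0806) or IFNa 18 (0.0633), and the classes that passed numbered 5, 5 and 3.

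**Figure D1:**
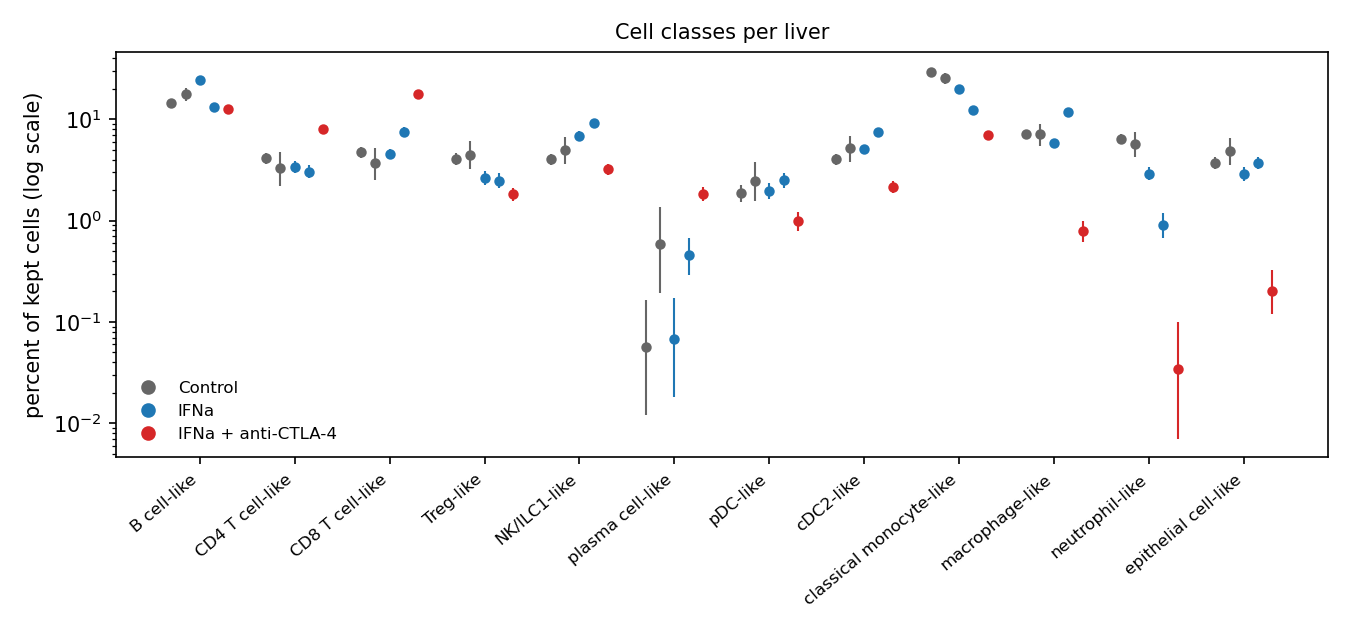
Percent of kept cells (log axis) in 12 cell classes, 1 point per liver coloured by group, with exact 95% intervals. Epithelial-like cells lie at 0.204% in the combination liver and between 2.89% and 4.86% in the other 4.

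Classical monocyte-like cells of the IFNa livers carried a broad interferon response: against Control, 1114 of 11966 genes changed, 697 up and 417 down. Of the 46 measured type I interferon genes, 45 rose (46 adjusted over the list alone), with a median log2 fold change of 2.09. Ifi44, an interferon-induced antiviral gene, rose most among them (log2 fold change 7.08 ± 0.43 SE, edgeR adjusted p = 0.000124). Siglec1, a sialic acid-binding macrophage receptor, rose 11.6-fold (log2 fold change 3.53 ± 0.16 SE, edgeR adjusted p = 4.61e-05), and Ifit3, an inhibitor of viral translation, rose 14.3-fold (ENSMUSG00000074896, chromosome 19, 34583531 to 34588731, GRCm38; log2 fold change 3.84 ± 0.32 SE, edgeR adjusted p = 0.000318). Slfn4, an interferon-induced Schlafen gene of myeloid cells (ENSMUSG00000000204, chromosome 11, 83175186 to 83190216), rose 24.2-fold (log2 fold change 4.60 ± 0.19 SE, edgeR adjusted p = 3.28e-05). Of 20 interferon-gamma-inducible genes 16 rose (18 adjusted over the list alone), including the GTPase Iigp1 (log2 fold change 5.17 ± 0.46 SE, edgeR adjusted p = 0.00044) and Cd274, which encodes the checkpoint ligand PD-L1 (ENSMUSG00000016496, chromosome 19, 29367455 to 29388095; log2 fold change 1.84 ± 0.20 SE, edgeR adjusted p = 0.00107). Of 19 MHC class I genes 17 rose (18 adjusted over the list alone), led by H2-Q7 (log2 fold change 3.72 ± 0.22 SE, edgeR adjusted p = 0.000124). None of the 11 MHC class II genes passed (0 adjusted over the list alone), with H2-Ab1 at a log2 fold change of 0.22 ± 0.29 that changed sign without IFNa 23 (-0.40).

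Monocyte chemokines and inflammatory genes moved with the interferon genes. Of 19 inflammatory genes 12 rose in classical monocyte-like cells (15 adjusted over the list alone), among them Ccl2 (log2 fold change 1.56 ± 0.19 SE, edgeR adjusted p = 0.0019) and Ccl7 (log2 fold change 2.08 ± 0.21 SE, edgeR adjusted p = 0.000786), which recruit monocytes, and Tnf (log2 fold change 1.60 ± 0.23 SE, edgeR adjusted p = 0.00489). The alternatively activated macrophage list divided: Il1rn, the interleukin-1 receptor antagonist, rose (log2 fold change 2.00 ± 0.22 SE, edgeR adjusted p = 0.00115), while Trem2, a lipid receptor of tumour macrophages, fell (log2 fold change -1.78 ± 0.22 SE, edgeR adjusted p = 0.00204) with 2 others, Ccl24 and Clec10a, of 17 (1 up and 4 down adjusted over the list alone). Arg1, the arginine-degrading enzyme of that list, was at 0.20 ± 0.22 on the log2 scale (edgeR adjusted p = 0.65). It rose with classes from marker scores (1.11, edgeR adjusted p = 0.0347) and changed sign without Control 11 (-0.10) or IFNa 23 (-0.0577). Fn1, the matrix protein fibronectin, fell (log2 fold change -1.90 ± 0.16 SE, edgeR adjusted p = 0.000362). Of 8 neutrophil transcripts 4 fell (5 down and 1 up adjusted over the list alone), with S100a8 (log2 fold change -3.69 ± 0.14 SE, edgeR adjusted p = 3.28e-05) and S100a9 (log2 fold change -4.04 ± 0.35 SE, edgeR adjusted p = 0.000404), the calprotectin subunits of neutrophils and young monocytes, while neutrophil-like cells were 1.91% of IFNa and 6.05% of Control livers. Of 17 proliferation genes 3 fell, among them Ube2c, with 8 down adjusted over the list alone.

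Of 11 IL-10 signalling genes in these cells 2 rose and 2 fell (the same counts adjusted over the list alone), of 9 Kupffer identity genes 2 rose (4 up and 2 down adjusted over the list alone), and none of 5 erythroid transcripts passed (0 adjusted over the list alone). Hepatocyte transcripts were among the changes, with 2 of 14 up and 1 down (5 and 1 adjusted over the list alone). Different clusters held most of the class: clusters 0 (59.1%) and 1 (37.0%) in Control, 37 (50.7%) and 11 (44.9%) in IFNa and 11 (60.9%) and 37 (38.6%) in the combination. Ly6i, Cfb, Cxcl9, Cxcl10 and Siglec1 were among the leading genes of cluster 11, Mmp8 of cluster 0, and Fn1 and Trem2 of cluster 1. The count of changed genes was 713 without Control 11.

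Macrophage-like cells changed in 330 of 11523 genes, 230 up and 100 down. All but 1 of 46 type I interferon genes rose (46 adjusted over the list alone; median log2 fold change 1.70), such as Ifi44 (log2 fold change 3.83 ± 0.23 SE, edgeR adjusted p = 3.17e-05) and Irf7, the transcription factor that amplifies interferon production (log2 fold change 2.39 ± 0.19 SE, edgeR adjusted p = 8.71e-05). The chemokines Cxcl10, a T cell attractant (ENSMUSG00000034855, chromosome 5, 92346638 to 92348889; log2 fold change 1.80 ± 0.29 SE, edgeR adjusted p = 0.00554), and Ccl5 (log2 fold change 2.11 ± 0.19 SE, edgeR adjusted p = 0.000148) rose. Of 21 interferon-gamma-inducible genes 9 rose and 1 fell (15 and 1 adjusted over the list alone), of 19 MHC class I genes 10 rose (19), and of 20 inflammatory genes 5 rose and 1 fell (6 and 2), the figures in brackets adjusted over the list alone. None of 11 MHC class II genes passed, with 1 up and 6 down adjusted over the list alone and H2-Ab1 at a log2 fold change of -0.54 ± 0.21. Of 19 alternative activation genes 3 fell (1 up and 5 down adjusted over the list alone), with the chemokine Ccl24 (log2 fold change -3.70 ± 0.53 SE, edgeR adjusted p = 0.00245) and the mannose receptor Mrc1 (log2 fold change -1.19 ± 0.23 SE, edgeR adjusted p = 0.0159). S100a8 (log2 fold change -3.14 ± 0.26 SE, edgeR adjusted p = 8.71e-05) and 1 other of 8 neutrophil transcripts fell (4 adjusted over the list alone), and 2 of 17 Kupffer genes rose (4 up and 1 down adjusted over the list alone). The count of changed genes was 157 without IFNa 23, and Mrc1 no longer passed without Control 25 or IFNa 18.

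Dendritic cells responded as well. In cDC2-like cells 350 of 10967 genes changed, 295 up and 55 down, and all 46 measured type I interferon genes rose (46 adjusted over the list alone; median log2 fold change 1.82), with Oasl1 at 3.79 ± 0.21 (edgeR adjusted p = 7.04e-05). Cxcl10 (log2 fold change 2.52 ± 0.19 SE, edgeR adjusted p = 0.000137), Il15, a growth factor of NK and CD8 T cells (log2 fold change 2.74 ± 0.32 SE, edgeR adjusted p = 0.00144), and the co-stimulatory receptor Cd40 (log2 fold change 1.39 ± 0.17 SE, edgeR adjusted p = 0.00158) rose. Of their 19 interferon-gamma-inducible genes 11 rose (19 adjusted over the list alone), of 19 MHC class I genes 13 (18) and of 17 inflammatory genes 5 (9), the figures in brackets adjusted over the list alone. pDC-like cells changed in 239 of 9642 genes, 151 up and 88 down, with 35 of 44 type I interferon genes up (40 adjusted over the list alone), including Isg15 (log2 fold change 3.44 ± 0.20 SE, edgeR adjusted p = 3.6e-06), and 10 of 19 MHC class I genes up (14). In pDC-like cells 4 of 11 MHC class II genes fell (6 adjusted over the list alone), such as H2-Aa (ENSMUSG00000036594, chromosome 17, 34282744 to 34287823; log2 fold change -1.17 ± 0.16 SE, edgeR adjusted p = 0.00118), and the neutrophil chemokine Cxcl2 fell (log2 fold change -5.71 ± 0.54 SE, edgeR adjusted p = 5.83e-05). H2-Aa did not pass with doublets kept. The pDC-like count was 366 without Control 25, 154 without IFNa 18 and 147 without IFNa 23.

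Non-classical monocyte-like cells changed in 148 of 7916 genes, 102 up and 46 down, with 39 of 46 type I interferon genes up (45 adjusted over the list alone) and Slfn4 at 4.38 ± 0.41 on the log2 scale (edgeR adjusted p = 0.000161). Their count was 809 without Control 25, 64 without IFNa 18 and 73 without IFNa 23, and DESeq2 put the share of changed genes that rose at 81.6% against 68.9% in edgeR. Mature dendritic cells had 3 changed genes of 6965, including Ifit3 (log2 fold change 3.60 ± 0.38 SE, edgeR adjusted p = 0.045) and Isg15 (log2 fold change 2.63 ± 0.26, edgeR adjusted p = 0.045), which were 2 of 45 type I interferon genes (38 adjusted over the list alone), and the apolipoprotein gene Apol7c. That count was 5 without Control 11, where neither Ifit3 nor Isg15 passed, 10 without Control 25, 38 without IFNa 18, 10 without IFNa 23 and 0 without the combination.

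Neutrophil-like cells of the IFNa livers differed in cluster mix and in some transcripts of dividing cells. Cluster 33, led by the granule genes Ngp, Camp and Ltf, held 12.2% of them in Control and 2.3% in IFNa. Of 13 proliferation genes 5 fell (12 adjusted over the list alone; median log2 fold change -3.18), with the division marker Mki67 at -4.05 ± 0.66 (edgeR adjusted p = 0.0132). Of 40 type I interferon genes 22 rose (38 adjusted over the list alone), and Cxcl10 rose strongly (log2 fold change 4.75 ± 0.40 SE, edgeR adjusted p = 0.000726). The granule protein gene Ngp, made by immature neutrophils, fell (log2 fold change -2.64 ± 0.46 SE, edgeR adjusted p = 0.018), a call lost without Control 25. In all 112 of 6189 genes changed, 51 up and 61 down, a count of 226 without Control 11, 219 without IFNa 18 and 585 without IFNa 23.

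B-like cells changed in 171 of 11200 genes, 136 up and 35 down. Of 45 type I interferon genes 43 rose (44 adjusted over the list alone; median log2 fold change 2.29), with Irf7 (log2 fold change 3.62 ± 0.15 SE, edgeR adjusted p = 9.33e-06) and Ifit3 (log2 fold change 3.86 ± 0.20 SE, edgeR adjusted p = 1.52e-05). The surface antigen gene Ly6c2 rose further (log2 fold change 4.73 ± 0.23 SE, edgeR adjusted p = 1.42e-05). Of 18 interferon-gamma-inducible genes 7 rose (12 adjusted over the list alone), including the GTPase Gbp6 (log2 fold change 2.40 ± 0.25 SE, edgeR adjusted p = 0.000744), and of 19 MHC class I genes 9 rose (16). Of 18 dissociation stress genes 4 fell (11 adjusted over the list alone), such as Dusp1 (log2 fold change -1.47 ± 0.19 SE, edgeR adjusted p = 0.00368) and Junb (log2 fold change -1.28 ± 0.16 SE, edgeR adjusted p = 0.00254), which respond within minutes to cell handling. The count was 459 without Control 11, 349 without Control 25 and 94 without IFNa 18.

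In NK-like cells 94 of 10467 genes changed, 80 up and 14 down, with 35 of 44 type I interferon genes up (42 adjusted over the list alone). Ifi27l2a, an interferon-induced mitochondrial protein (log2 fold change 4.57 ± 0.21 SE, edgeR adjusted p = 4.73e-11), and Ly6a, the Sca-1 antigen (log2 fold change 2.90 ± 0.23 SE, edgeR adjusted p = 3.5e-07), rose. Gzmb, which encodes granzyme B of killer lymphocytes, rose (log2 fold change 1.43 ± 0.21 SE, edgeR adjusted p = 0.00045) as the only 1 of 18 cytotoxic genes to pass (1 adjusted over the list alone), and it did not pass in DESeq2. Of 18 interferon-gamma-inducible genes 3 rose (12 adjusted over the list alone), and 3 of 17 stress genes fell (6). In DESeq2 98.2% of the changed genes rose, against 85.1% in edgeR.

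T cells showed the interferon response with few genes past the threshold. CD8 T cell-like cells had 3 changed genes of 10373, although 39 of 43 type I interferon genes passed adjusted over the list alone (2 over all genes; median log2 fold change 1.43). These were the interferon-induced modifier Isg15 (log2 fold change 2.33 ± 0.27 SE, edgeR adjusted p = 0.0385) and its protease Usp18 (log2 fold change 2.64 ± 0.32 SE, edgeR adjusted p = 0.0385), and the receptor segment Trbv5 fell. None of 15 exhaustion genes passed (0 adjusted over the list alone; median log2 fold change 0.62), with Pdcd1, which encodes PD-1, at 0.56 ± 0.42 and Tox at 0.59 ± 0.54. Without IFNa 23 that median (-0.34), Pdcd1 (-0.34) and Tox (-0.15) changed sign, as Tox did without Control 25. The median was 1.93 without Control 11. Ifng was at 1.74 ± 0.41 (edgeR adjusted p = 0.347) and Gzmb at 1.31 ± 0.59. Ifng passed in DESeq2 (adjusted p = 0.0361), and both passed in edgeR without a filter on low counts (adjusted p = 3.88e-06 and 0.00343) and without IFNa 18 (3.53e-08 and 1.81e-05). None of 18 cytotoxic, 14 naive or 14 proliferation genes passed (1 up and 1 down, 1 up, and 0 adjusted over the list alone). The CD8 count was 8 without Control 11, 1 without Control 25, 313 without IFNa 18, 64 without IFNa 23 and 0 without the combination. Isg15 did not pass without Control 11, and neither Isg15 nor Usp18 passed without Control 25 or the combination. Pooled over the livers of a group, the largest cluster of CD8 T cell-like cells was 6 in Control (43.7%) and 16 in IFNa (32.4%). In the combination it was 16 (35.1%, beside 32.6% in cluster 29). Of all cells of cluster 16, 214 came from IFNa 23 and 32 from IFNa 18, so its place in IFNa rests mostly on IFNa 23. Control 11 gave 255 and Control 25 gave 31 of the CD8 T cell-like cells. The leading genes of cluster 16 include Lag3, Rgs16 and Prf1.

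CD4 T cell-like cells changed in 32 of 9405 genes, 30 up and 2 down, with 16 of 43 type I interferon genes up (38 adjusted over the list alone). The chemokine genes Ccl4 (log2 fold change 6.24 ± 0.63 SE, edgeR adjusted p = 0.00294) and Ccl3 (log2 fold change 6.33 ± 0.76 SE, edgeR adjusted p = 0.00418) rose, the 2 of 16 cytotoxic genes to pass (11 adjusted over the list alone). None of 14 type 1 regulatory T cell genes passed (1 adjusted over the list alone), and 1 of 17 stress genes fell (6). The CD4 count was 2 without Control 11, where Ccl3 and Ccl4 no longer passed, 53 without Control 25, 236 without IFNa 18 and 18 without the combination. Pooled over the livers of a group, the largest cluster of CD4 T cell-like cells was 6 in Control (66.3%) and IFNa (37.4%, beside 33.8% in cluster 14). In the combination it was 14 (45.7%, beside 37.0% in cluster 27). The IFNa livers differed: subclusters with Ccr7 in at least 50% of cells held 52.5% of these cells in IFNa 18 and 17.3% in IFNa 23. Regulatory T cell-like cells changed in 52 of 9633 genes, with 24 of 42 type I interferon genes up (41 adjusted over the list alone), such as Usp18 (log2 fold change 2.80 ± 0.24 SE, edgeR adjusted p = 0.000497). None of their 15 identity genes passed (0 adjusted over the list alone; median log2 fold change 0.0597, mean -0.0397), and Foxp3, the master regulator of these cells, was at -0.20 ± 0.17. Of 16 stress genes 2 fell (7 adjusted over the list alone), and 13 genes changed without IFNa 18.

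Epithelial-like cells had no changed gene of 12947 in edgeR, with 717 at an unadjusted p under 0.05 and 3 changed in DESeq2. Adjusted over the list alone 31 of 46 type I interferon genes passed (0 over all genes; median log2 fold change 1.08). Of 20 interferon-gamma-inducible genes 3, of 11 MHC class II genes 4, of 19 MHC class I genes 0 and of 12 colorectal cancer transcripts 0 passed adjusted over the list alone, and none over all genes. The median UMI count of these cells was 20488 and 23008 in Control and 21178 in IFNa 18, against 3530 in IFNa 23. Cluster 42 held 25.6% of the pooled IFNa cells, 93 of them from IFNa 23 and 1 from IFNa 18. The count was 5 without Control 11, 433 without IFNa 18 and 5 without IFNa 23.

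**Figure D2:**
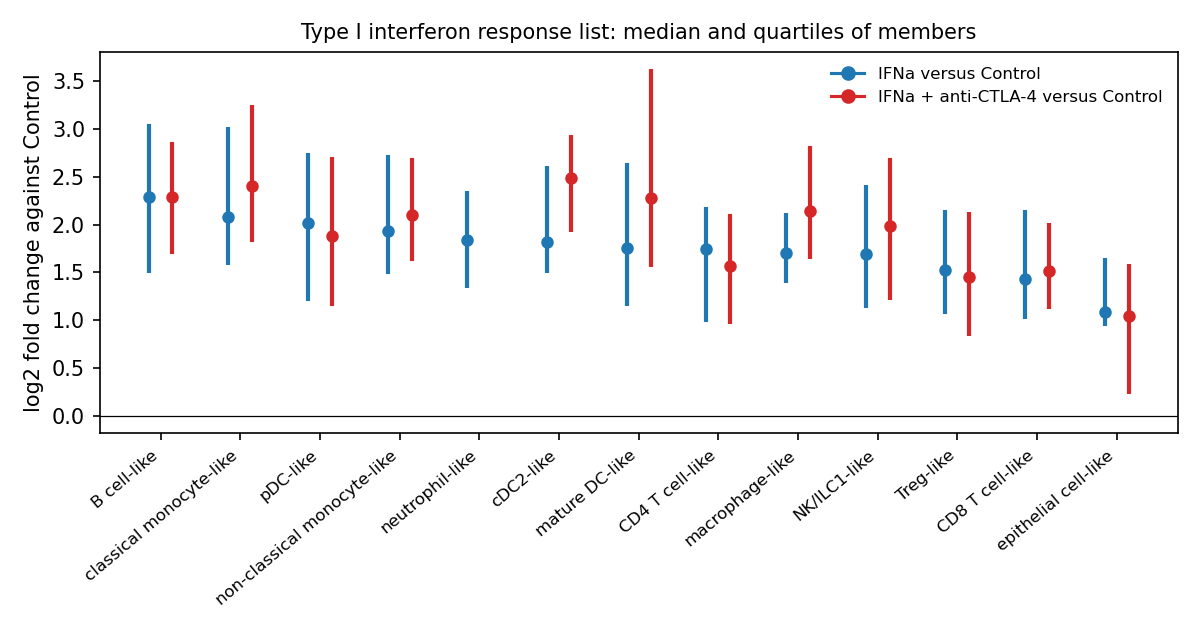
Log2 fold change against Control of type I interferon list members per cell class, for IFNa and for the combination, points being medians and bars quartiles. The IFNa medians run from 1.08 in epithelial-like to 2.29 in B-like cells.

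No list and class pair passed fry over the 225 pairs of IFNa against Control (smallest fry adjusted p = 0.143; 49 at an unadjusted p under 0.05). Camera with a preset correlation called 108 pairs, and none with an estimated correlation, where the smallest adjusted p was 0.339. Without Control 11, fry called 3 pairs. So the list counts rest on single genes, and no list passed as a set.

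The IFNa effect was compared between classes by testing the interaction of class and group against CD8 T cell-like cells. The type I interferon list rose more in cDC2-like cells by a median log2 of 0.478 (fry adjusted p = 0.0202) and in pDC-like cells by 0.344 (fry adjusted p = 0.0202). Neither call held with doublets kept (0.141 and 0.806), without Control 11 (0.194 in both), Control 25 (0.134 in both), IFNa 18 (0.342 and 0.089) or IFNa 23 (0.363 and 0.278), nor did cDC2 without the combination (0.0742). B-like (0.547, fry adjusted p = 0.0713) and non-classical monocyte-like cells (0.65, fry adjusted p = 0.0713) did not pass, nor did classical monocyte-like cells (0.65, fry adjusted p = 0.225) or epithelial-like cells (-0.29, fry adjusted p = 0.704). Single genes with another effect than in CD8 T cell-like cells numbered 186 in classical monocyte-like cells. That count was 1 without Control 11, 11 without Control 25, 345 without IFNa 18, 63 without the combination and 424 with doublets kept.

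In the combination liver nearly all interferon-gamma-inducible genes lay above Control in classical monocyte-like, macrophage-like and cDC2-like cells. Classical monocyte-like cells changed against Control in 1483 genes, 1019 up and 464 down, with the 1 combination library assumed to vary like the other groups. All 20 interferon-gamma-inducible genes rose (20 adjusted over the list alone; median log2 fold change 3.47), including Cd274 (log2 fold change 3.44 ± 0.22 SE, edgeR adjusted p = 0.000113) and Nos2, the inducible nitric oxide synthase (ENSMUSG00000020826, chromosome 11, 78920787 to 78960254; log2 fold change 6.57 ± 0.39 SE, edgeR adjusted p = 0.000109; 417 UMIs against 16 in Control). Of 11 MHC class II genes 6 rose (8 adjusted over the list alone), with H2-Ab1 at 1.82 ± 0.35 (edgeR adjusted p = 0.0117), a call lost with classes from marker scores. Arg1 fell (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484; log2 fold change -2.69 ± 0.35 SE, edgeR adjusted p = 0.00191) with Trem2 (log2 fold change -2.50 ± 0.30 SE, edgeR adjusted p = 0.00145), among 5 of 17 alternative activation genes down and 1 up (7 and 1 adjusted over the list alone). Fn1 (log2 fold change -3.22 ± 0.23 SE, edgeR adjusted p = 0.000146) and S100a8 (ENSMUSG00000056054, chromosome 3, 90668978 to 90670035; log2 fold change -7.02 ± 0.25 SE, edgeR adjusted p = 1.6e-05) fell, beside a neutrophil-like share of 0.0340% against 6.05%. Of 46 type I interferon genes 45 rose (46 adjusted over the list alone; median log2 fold change 2.41), and of 19 MHC class I genes 18 (18).

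Macrophage-like cells changed in 528 genes, 381 up and 147 down, and cDC2-like cells in 696, 530 up and 166 down, with the 1 combination library assumed to vary like the other groups in both. In macrophage-like cells 19 of 21 interferon-gamma-inducible genes rose (21 adjusted over the list alone), with Cxcl10 (log2 fold change 3.35 ± 0.33 SE, edgeR adjusted p = 0.000165), while Ccl5 rose 17.1-fold (log2 fold change 4.10 ± 0.22 SE, edgeR adjusted p = 7.16e-06). Of 19 alternative activation genes 6 fell and 1 rose (10 and 1 adjusted over the list alone), such as Arg1 (log2 fold change -2.00 ± 0.30 SE, edgeR adjusted p = 0.00237), Mrc1 (log2 fold change -2.40 ± 0.40 SE, edgeR adjusted p = 0.0044) and Spp1, the matrix protein osteopontin (log2 fold change -2.97 ± 0.43 SE, edgeR adjusted p = 0.00187). In cDC2-like cells all 19 interferon-gamma-inducible genes rose (19 adjusted over the list alone), with Cxcl10 (log2 fold change 4.71 ± 0.21 SE, edgeR adjusted p = 2.37e-05), and so did Cd40 (log2 fold change 2.40 ± 0.19 SE, edgeR adjusted p = 0.000121). The lectin gene Mgl2 (log2 fold change -2.44 ± 0.20 SE, edgeR adjusted p = 0.000131) was among 4 of 16 alternative activation genes down, with 1 up (7 and 1 adjusted over the list alone). Type I interferon genes rose in 45 of 46 in macrophage-like (45 adjusted over the list alone) and 46 of 46 in cDC2-like cells (46), and MHC class I genes in 18 of 19 in both (19 and 18).

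**Figure D3:**
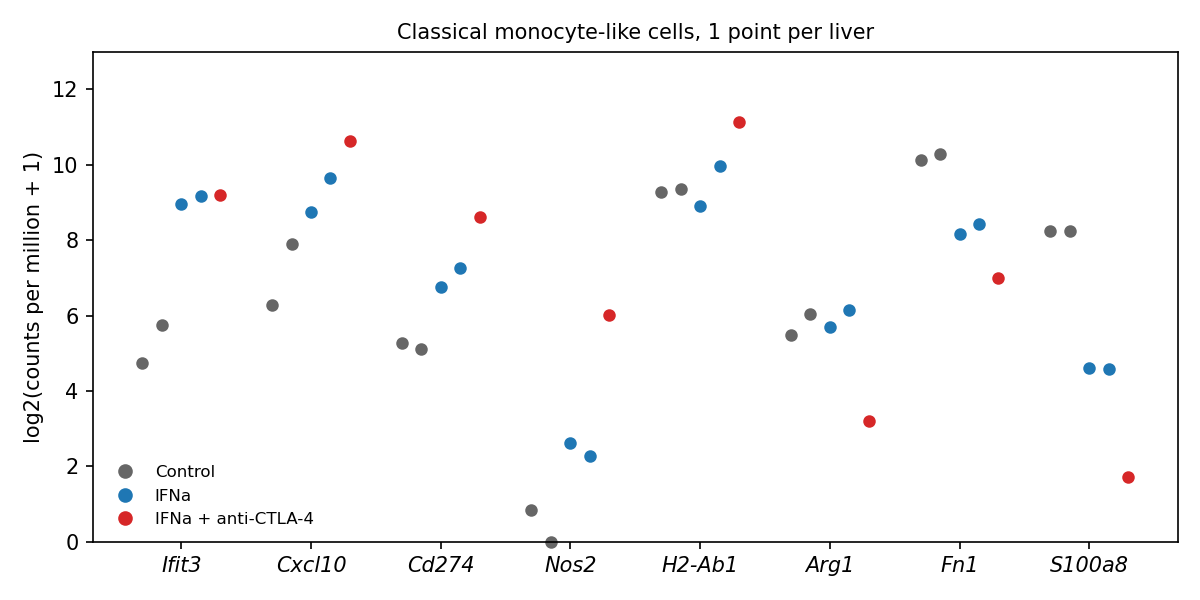
Log2 CPM of 8 genes in classical monocyte-like cells, 1 point per liver grouped by treatment. Nos2 and Cd274 lie highest and Arg1, Fn1 and S100a8 lowest in the combination liver.

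In lymphocytes of the combination liver, with the 1 library assumed to vary like the other groups in each count, B-like cells changed in 245 genes against Control, 184 up and 61 down. Of their 18 interferon-gamma-inducible genes 15 rose (15 adjusted over the list alone), with Gbp6 (log2 fold change 3.88 ± 0.24 SE, edgeR adjusted p = 3.87e-05), and of 19 MHC class I genes 13 rose (17), with Nlrc5, the transactivator of MHC class I (log2 fold change 1.68 ± 0.20 SE, edgeR adjusted p = 0.00169). Of 45 type I interferon genes 41 rose (44). NK-like cells changed in 140 genes, 108 up and 32 down, with Ifi27l2a (log2 fold change 4.84 ± 0.23 SE, edgeR adjusted p = 6.16e-11). Cluster 26, led by Gzmc, held 31.1% of them against 11.6% in Control. Cd8b1, a CD8 T cell gene, was at least 31.0-fold higher in NK-like cells, with 108 UMIs against 0 in the Control group and a limit of 3 counts over the group. A TRB chain was found in 7.77% of their barcodes (exact 95% interval 4.94 to 11.5), against 1.85% and 0% in Control. Immunoglobulin made up 0.0848% of NK-like UMIs (Control 0.0131% and 0.0199%) and 0.0547% of CD8 T cell-like UMIs (Control 0.0145% and 0.0164%). Regulatory T cell-like cells changed in 74 genes, with Lrrc32, which displays latent TGF-beta (log2 fold change 2.39 ± 0.26 SE, edgeR adjusted p = 0.00206), and Klrg1 (log2 fold change -1.62 ± 0.23 SE, edgeR adjusted p = 0.0102). CD8 T cell-like cells had 4 changed genes, Usp18 (log2 fold change 2.74 ± 0.35 SE, edgeR adjusted p = 0.0453), Isg15 and the immunoglobulin segment Igkv4-59 up and the heat shock gene Hspa1a down, with 2 of 43 type I interferon genes up (39 adjusted over the list alone).

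Counts of the combination against Control moved with single libraries. The B-like count was 820 without Control 11 and 611 without Control 25, and the CD8 T cell-like count 285 without IFNa 18 and 294 without IFNa 23, while Usp18 in CD8 did not pass without Control 11 or Control 25. In NK-like cells the share of changed genes that rose was 77.1% in edgeR and 88.3% in DESeq2.

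Epithelial-like cells of the combination (18 cells, assumed to vary like the other groups) had 14 changed genes against Control, 13 up and 1 down. Among them were 4 of 11 MHC class II genes (8 adjusted over the list alone; median log2 fold change 3.84), which present antigen to CD4 T cells: H2-Aa (log2 fold change 4.35 ± 0.46 SE, edgeR adjusted p = 0.0462), H2-Eb1 (log2 fold change 4.77 ± 0.53 SE, edgeR adjusted p = 0.0462), H2-Ab1 and Cd74. Ido1, the tryptophan-degrading enzyme, rose (log2 fold change 4.41 ± 0.45 SE, edgeR adjusted p = 0.0462), the only 1 of 20 interferon-gamma-inducible genes past the threshold over all genes (18 adjusted over the list alone). None of 46 type I interferon genes passed (10 adjusted over the list alone), nor any of 19 MHC class I genes (18). The median log2 fold change over all tested genes was -0.177 in this class, so these changes are measured against a lowered baseline. With doublets kept H2-Aa (2.88, edgeR adjusted p = 0.175) and H2-Eb1 (3.03, edgeR adjusted p = 0.246) did not pass. H2-Aa also failed with classes from marker scores (edgeR adjusted p = 0.0674). Neither they nor Ido1 passed without a filter on low counts, where the count was 0. Without Control 11 or Control 25 no gene passed in edgeR, and without IFNa 18 or IFNa 23 the count was 220 or 207.

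Over the 208 list and class pairs of the combination against Control no pair passed fry (smallest fry adjusted p = 0.104; 49 at an unadjusted p under 0.05). Camera with a preset correlation called 102, and none with an estimated correlation (smallest adjusted p = 0.356). Without Control 25, fry called 1 pair.

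Against IFNa alone, part of the interferon-gamma-inducible genes rose in myeloid cells of the combination, while no list passed as a set. Classical monocyte-like cells changed in 118 genes, 100 up and 18 down, with the 1 combination library assumed to vary like the other groups. Of 20 interferon-gamma-inducible genes 7 rose (20 adjusted over the list alone; median log2 fold change 1.58), with Cd274 (log2 fold change 1.60 ± 0.21 SE, edgeR adjusted p = 0.0204) and Gbp5 (log2 fold change 2.16 ± 0.31 SE, edgeR adjusted p = 0.0272). Of 46 type I interferon genes none passed (0 adjusted over the list alone; median log2 fold change 0.23). Arg1 fell (log2 fold change -2.88 ± 0.35 SE, edgeR adjusted p = 0.0136), 1 of 17 alternative activation genes, with 1 up (1 and 1 adjusted over the list alone). Macrophage-like cells changed in 79 genes, 67 up and 12 down, under the same assumption for the 1 combination library. In them 10 of 21 interferon-gamma-inducible genes rose (20 adjusted over the list alone), with Nos2 (log2 fold change 3.57 ± 0.26 SE, edgeR adjusted p = 0.000237) and Cd274 (log2 fold change 1.69 ± 0.21 SE, edgeR adjusted p = 0.00494), and none of 19 alternative activation genes passed (1 up and 6 down adjusted over the list alone). Of their 46 type I interferon genes 2 rose (6 adjusted over the list alone; median log2 fold change 0.43). Cd3e, a T cell receptor component, was also higher in macrophage-like cells (log2 fold change 3.92 ± 0.55 SE, edgeR adjusted p = 0.00891), and a TRB chain was found in 4.29% of their barcodes against 0.29% and 0.48% in IFNa.

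The monocyte count was 328 and 380 without Control 11 and Control 25, and 345 and 363 without IFNa 18 and IFNa 23. The macrophage count was 157, 150 and 26 without Control 11, Control 25 and IFNa 18, and Cd3e did not pass without IFNa 18 or with doublets kept and changed sign with classes from marker scores (-1.23). In classical monocyte-like cells the share of changed genes that rose was 84.7% in edgeR and 72.9% in DESeq2.

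In cDC2-like cells 34 genes changed against IFNa, 23 up and 11 down, with Cxcl10 up (log2 fold change 2.19 ± 0.18 SE, edgeR adjusted p = 0.007), and 3 of 19 interferon-gamma-inducible genes rose (19 adjusted over the list alone), with none of 46 type I interferon genes (19 adjusted over the list alone; median log2 fold change 0.41). B-like cells had 42 changed genes, 35 up and 7 down, with the protease inhibitor Slpi (log2 fold change 4.05 ± 0.25 SE, edgeR adjusted p = 0.000456) and 8 of 18 interferon-gamma-inducible genes up (15 adjusted over the list alone). In each of these counts the 1 combination library is assumed to vary like the other groups. CD8 T cell-like cells had 1 changed gene, the immunoglobulin segment Igkv4-59 of plasma cells and B cells, and none of 43 type I interferon genes passed (0 adjusted over the list alone; median log2 fold change 0.0443, mean -0.0167). Epithelial-like cells had 3, C1s1, Inf2 and Ubd, with none of 20 interferon-gamma-inducible or 11 MHC class II genes past the threshold (12 and 8 adjusted over the list alone) and a median over all genes of -0.159. The cDC2 count was 85, 56, 174 and 210 without Control 11, Control 25, IFNa 18 and IFNa 23, and the B-like count 297, 328, 2 and 22. The CD8 count was 12, 14, 60 and 202 in the same order, and the epithelial count 0, 0, 141 and 122. In B-like cells 83.3% of the changed genes rose in edgeR and 68.2% in DESeq2.

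Over the 208 list and class pairs of the combination against IFNa none passed fry (smallest fry adjusted p = 0.391; 25 at an unadjusted p under 0.05). Camera with a preset correlation called 85, and none with an estimated correlation (smallest adjusted p = 0.573). Without IFNa 18, fry called 1 pair.

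Expanded T cell clonotypes took their largest shares in liver IFNa 23 and the combination. Such clonotypes, of 2 or more barcodes, held 60.0% of paired barcodes in the combination (exact 95% interval 58.2 to 61.8) and 52.7% in IFNa 23, against 31.6% in IFNa 18 and 31.0% and 14.2% in Control 11 and 25. Barcode number sets part of these gaps and most of that from IFNa 23 to the combination. Thinned to 106 barcodes, the shares were 31.1% in the combination, 31.0% in IFNa 23, 17.99% in IFNa 18, and 16.3% and 14.2% in Control 11 and 25. The group means were then 24.5% ± 9.21 (SD, n = 2) in IFNa and 15.2% ± 1.52 (SD, n = 2) in Control. The largest clonotype took 16.7% of barcodes in IFNa 23 and 7.83% in the combination, against 4.69% in IFNa 18 and 5.56% and 2.83% in Control.

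Among CD8 T cell-like cells 72.4% of combination barcodes and 64.4% of IFNa 23 barcodes were in expanded clonotypes, against 22.1% in IFNa 18 and 25.8% and 14.3% in Control. Thinned to 28 barcodes, these became 32.5%, 39.4%, 7.89%, 15.3% and 14.3%. CD4 T cell-like cells reached 43.3% in the combination, 36.5% in IFNa 23, 12.0% in IFNa 18 and 1.30% in Control 11, or 22.6%, 36.5%, 11.7% and 1.18% thinned to 137. Control 25 had too few CD4 barcodes for a value. Regulatory T cell-like cells showed no such order, with 26.4% in the combination, 62.7% and 48.6% in IFNa and 50.0% and 13.8% in Control. Thinned to 29, these were 11.6%, 47.6%, 28.1%, 23.6% and 13.8%. With 2, 2 and 1 libraries these values were not tested.

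**Figure D4:**
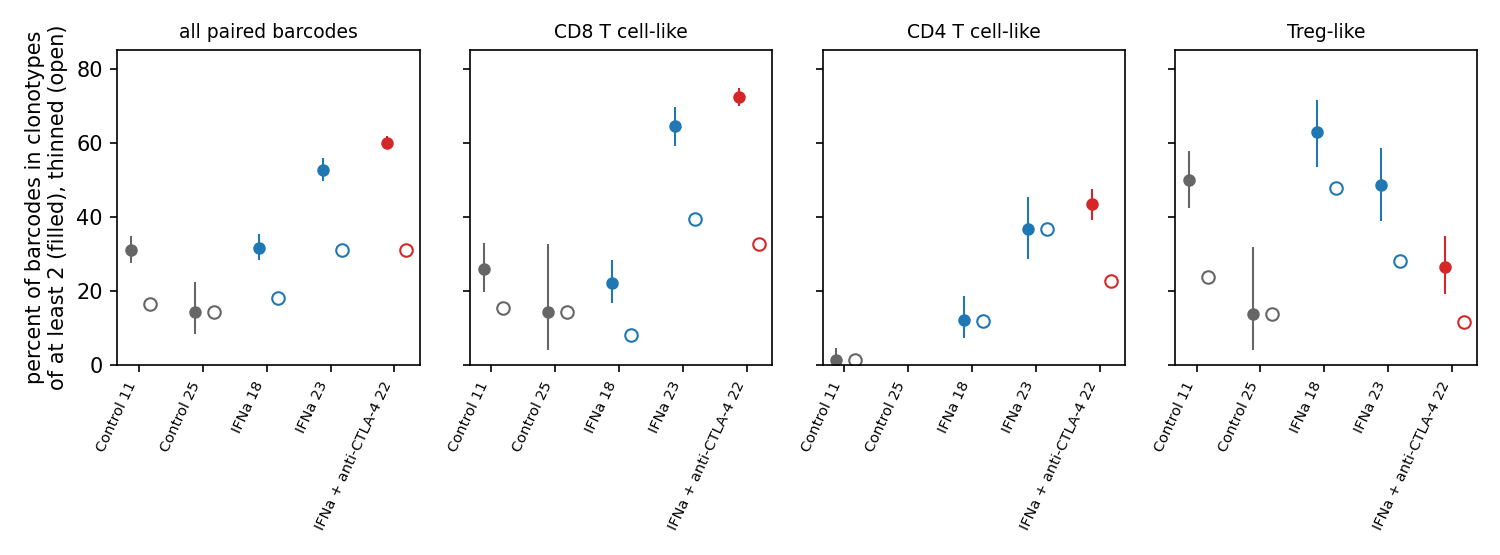
Percent of paired barcodes in clonotypes of at least 2 barcodes, per liver, for all barcodes and for CD8, CD4 and regulatory T cell-like cells, filled points with exact 95% intervals for all barcodes and open points after thinning. In CD8 T cell-like cells the filled points reach 64.4% in IFNa 23 and 72.4% in the combination.

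Invariant T cells, which recognise lipid or vitamin B metabolites with a fixed receptor, were scored by their TRA genes. Invariant NKT receptors made up 1.24% (9 of 729) and 3.54% (4 of 113) of TRA barcodes in Control, 2.51% and 1.75% in IFNa and 1.59% in the combination. The exact 95% intervals of the Control shares, 0.566 to 2.33 and 0.973 to 8.82, covered the other 3 values except 2.51% for the first. MAIT receptors were found in 3 and 0 barcodes of Control, 0 and 4 of IFNa and 5 of the combination. The counts of 0 allow shares of up to 2.65% in Control 25 and 0.418% in IFNa 18.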

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

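The tests of free neutrophil RNA, of the cells with most S100a8 and S100a9, and of dilution by T cells were chosen only after the result was seen. S100a8 and S100a9 were lower in monocyte-like and macrophage-like cells with IFNa. For S100a8 in monocyte-like cells of Control 11 and 25, free neutrophil RNA is argued against by levels 29.3 and 114 times the median of 6 lymphoid and pDC-like classes (lower bounds 21.97 and 13.1), and neutrophils by 6.02 and 9.89 times (5.27 and 6.57) without the 83 of 1586 and 7 of 215 cells with most UMIs of both genes. For S100a9 there, immature neutrophils are argued against by a fraction of the neutrophil-like level 26.3 and 234 times that of the granule genes Ngp, Camp and Ltf, but free RNA cannot be told apart from expression (11.2 and 48.5 times, lower bounds 5.67 and 0.751). Mature neutrophils cannot be told apart either: S100a9 fell to 0.655 and 0.826 times on that removal, as skewed expression in monocytes would also give, and the leading genes of mature neutrophils reached 0.629 and 0.856 of the level needed, or 0.414 and 0.258 with the need taken from the largest neutrophil-like cluster. In macrophage-like cells neither can be told apart: S100a8 stood at 3.89 and 14.2 times (lower bounds 0.438 and 3.08), then at 0.497 without 3 of 382 and 10.1 (lower bound 1.53) without 1 of 60 cells, and the leading genes reached up to 8.22 times the need. A change of monocyte state with interferon or another mix of monocyte maturity may also underlie the pattern and stays open and untested.

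MHC class II transcripts were higher in the 18 epithelial-like cells of the combination liver. RNA from monocytes or macrophages is argued against: their own genes reached at most 0.0450 of the fraction that MHC class II reached. B cell RNA is argued against as well, since B cell genes reached 2.86% (upper bound 3.66%) of the B-like level against 24.8% for MHC class II, a ratio of 0.115. Dendritic cell RNA cannot be told apart from expression by the epithelial-like cells, because the dendritic genes reached 0.398 of the MHC class II fraction from 15 UMIs, with an upper bound of 12.3% of the cDC2-like level against 18.6% for MHC class II. An interferon-gamma response of the epithelial-like cells may also account for the rise and was not tested apart from it.

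Epithelial-like cells were fewer in the combination liver. Dilution by T cells is argued against as the whole cause, since among named cells neither T nor NK-like the log2 ratio was still -2.92 ± 0.866 (SE, edgeR adjusted p = 0.0101). Loss of intact cells into unnamed droplets is argued against too. Epithelial transcripts there amounted to 3.16 cell equivalents, 0.880% of the 358.8 missing cells by the mean Control share. Loss with little RNA left cannot be told (median UMIs 1528 there, 10580 in epithelial-like cells). Fewer tumour cells after combined treatment, a smaller metastasis in that sample or a lower yield on digestion stay open and untested with 1 liver.

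Further values stood out because the IFNa effect differed between cell classes in a test of the difference itself, or because cells lay outside every class. Genes with another IFNa effect than in CD8 T cell-like cells numbered 14 in B-like, 20 in CD4 T cell-like, 3 in NK-like and 2 in regulatory T cell-like cells. They numbered 23 in cDC2-like, 22 in pDC-like, 12 in mature dendritic, 15 in macrophage-like, 36 in non-classical monocyte-like, 41 in neutrophil-like, 45 in epithelial-like and 186 in classical monocyte-like cells. With 1 library left out they ran from 0 to 221 in B-like, 0 to 51 in CD4, 0 to 92 in NK-like, 1 to 79 in regulatory T cell-like and 1 to 345 in classical monocyte-like cells. The type I interferon list differed by a median log2 of 0.478 in cDC2-like and 0.344 in pDC-like cells, calls lost with doublets kept (fry adjusted p = 0.141 and 0.806) and without any 1 of the Control or IFNa libraries. Unnamed clusters held 7.29% and 10.5% of the cells of IFNa 18 and 23 and 34.4% of the combination, above 5.46% and 2.49% in Control.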

How the results depend on the processing

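Chosen after seeing the data were the settings without receptor segment genes, with monocytes and macrophages merged, without naive-like clusters, and with named cells other than T and NK as denominator. Of 1024 values of single genes under the alternatives, 977 kept their direction and their side of 0.05, 34 lost significance, 6 gained it and 7 changed sign. Of 679 list medians 656 stayed, 2 gained significance and 21 changed sign. Of 212 class share ratios 149 stayed, 59 lost significance, 1 gained it and 3 changed sign. Of 112 T cell receptor values 107 stayed within the reported exact interval, and amino acid clonotypes and paired barcodes as denominator moved none. A minimum of 30 cells moved none of the 23 gene counts it could be run on, but it could hardly do so. Outside epithelial-like cells, every library used in those classes already held more than 30 cells, so the fits were unchanged. The 78 gene values under that minimum come from such unchanged fits. In epithelial-like cells it drops the combination (18 cells), so only IFNa against Control was run there. That minimum was not run in CD4 T, mature DC, non-classical monocyte and pDC classes, where it drops Control 25 and so equals leaving that library out. No paired analysis was possible because the livers of different groups share no sample number. Control 25, with 863 cells, limits many small classes, while the combination held fewer cells still in some, with 18 epithelial-like and 3 neutrophil-like cells. In simulated counts edgeR recovered 25% and 33% of 1 log2 unit changes in CD8 T and epithelial-like cells for IFNa against Control. Those counts left out variation particular to single genes and changed only genes of at least 20 CPM. Recovery in the data may be lower, so these figures do not bound the absence of a change.

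Counts of changed genes depended on the processing, and the cause was not tested unless stated. IFNa against Control gave, in edgeR, 171 changed genes in B, 32 in CD4 T, 3 in CD8 T, 94 in NK or ILC1, 52 in Treg, 350 in cDC2, 1114 in classical monocyte, 0 in epithelial, 3 in mature DC, 330 in macrophage, 112 in neutrophil, 148 in non-classical monocyte and 239 in pDC cells. The combination against Control gave, in edgeR, 245 changed genes in B, 12 in CD4 T, 4 in CD8 T, 140 in NK or ILC1, 74 in Treg, 696 in cDC2, 1483 in classical monocyte, 14 in epithelial, 44 in mature DC, 528 in macrophage, 106 in non-classical monocyte and 208 in pDC cells. The combination against IFNa gave, in edgeR, 42 changed genes in B, 2 in CD4 T, 1 in CD8 T, 50 in NK or ILC1, 21 in Treg, 34 in cDC2, 118 in classical monocyte, 3 in epithelial, 0 in mature DC, 79 in macrophage, 4 in non-classical monocyte and 0 in pDC cells. The DESeq2 Wald test gave for IFNa against Control 26 in CD8 T, 55 in NK or ILC1, 3 in epithelial, 22 in mature DC, 87 in non-classical monocyte and 128 in pDC cells. The DESeq2 Wald test gave for the combination against Control 20 in CD4 T, 15 in CD8 T, 60 in NK or ILC1, 41 in Treg, 451 in cDC2, 94 in epithelial, 100 in mature DC, 64 in non-classical monocyte and 112 in pDC cells. The DESeq2 Wald test gave for the combination against IFNa 22 in B, 1 in CD4 T, 3 in CD8 T, 8 in NK or ILC1, 11 in Treg, 50 in epithelial, 2 in mature DC, 0 in non-classical monocyte and 2 in pDC cells. RLE size factors gave for the combination against IFNa 79 in cDC2 cells. Without a filter on low counts, IFNa against Control reached 465 in B, 195 in CD4 T, 152 in CD8 T, 169 in NK or ILC1, 173 in Treg, 826 in cDC2, 1871 in classical monocyte, 172 in mature DC, 706 in macrophage, 343 in neutrophil, 332 in non-classical monocyte and 456 in pDC cells. Without a filter on low counts, the combination against Control reached 676 in B, 250 in CD4 T, 276 in CD8 T, 270 in NK or ILC1, 310 in Treg, 1256 in cDC2, 2260 in classical monocyte, 0 in epithelial, 417 in mature DC, 955 in macrophage, 241 in non-classical monocyte and 465 in pDC cells. Without a filter on low counts, the combination against IFNa reached 300 in B, 57 in CD4 T, 90 in CD8 T, 104 in NK or ILC1, 193 in Treg, 425 in cDC2, 648 in classical monocyte, 0 in epithelial, 130 in mature DC, 361 in macrophage, 38 in non-classical monocyte and 56 in pDC cells. With doublets kept, IFNa against Control reached 14 in CD8 T, 7 in mature DC and 206 in neutrophil cells. The combination against Control then reached 36 in CD4 T, 0 in CD8 T and 69 in non-classical monocyte cells. With doublets kept, the combination against IFNa reached 27 in B, 6 in CD4 T, 2 in CD8 T, 253 in classical monocyte, 10 in epithelial, 21 in mature DC and 0 in non-classical monocyte cells. Classes from marker scores gave for IFNa against Control 12 in CD4 T, 13 in CD8 T, 27 in Treg, 191 in cDC2, 27 in mature DC, 46 in neutrophil, 581 in non-classical monocyte and 148 in pDC cells. Classes from marker scores gave for the combination against Control 29 in CD8 T, 387 in cDC2, 1017 in epithelial, 106 in mature DC and 699 in non-classical monocyte cells. Classes from marker scores gave for the combination against IFNa 1 in B, 12 in CD4 T, 23 in CD8 T, 26 in NK or ILC1, 33 in Treg, 25 in classical monocyte, 32 in epithelial, 18 in mature DC, 220 in macrophage, 105 in non-classical monocyte and 38 in pDC cells. Without receptor segment genes, IFNa against Control left 13 in CD8 T cells. The combination against Control then left 410 in B and 23 in CD4 T cells. Against IFNa it left 110 in B, 0 in CD4 T, 0 in CD8 T and 20 in NK or ILC1 cells. With monocytes and macrophages merged, counts were 769 for IFNa against Control, 1154 for the combination against Control and 187 for the combination against IFNa. Without naive-like clusters, IFNa against Control gave 7 in CD8 T cells. The combination against IFNa then gave 13 in CD4 T and 0 in CD8 T cells.

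With 1 library left out at a time, a lone library left in a group is assumed to vary like the other groups, and the cause was not tested. Counts for IFNa against Control then ran from 94 to 459 in B, from 2 to 236 in CD4 T, from 0 to 313 in CD8 T, from 13 to 61 in Treg, from 713 to 1381 in classical monocyte, from 0 to 433 in epithelial, from 0 to 38 in mature DC, from 157 to 291 in macrophage, from 106 to 585 in neutrophil, from 64 to 809 in non-classical monocyte and from 147 to 366 in pDC cells. Counts for the combination against Control then ran from 177 to 820 in B, from 0 to 199 in CD4 T, from 5 to 294 in CD8 T, from 0 to 220 in epithelial, from 47 to 124 in mature DC, from 106 to 440 in non-classical monocyte and from 204 to 411 in pDC cells. Counts for the combination against IFNa then ran from 2 to 328 in B, from 11 to 44 in CD4 T, from 12 to 202 in CD8 T, from 40 to 93 in NK or ILC1, from 4 to 76 in Treg, from 56 to 210 in cDC2, from 328 to 380 in classical monocyte, from 0 to 141 in epithelial, from 1 to 4 in mature DC, from 26 to 157 in macrophage, from 6 to 34 in non-classical monocyte and from 5 to 70 in pDC cells.

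Genes whose IFNa effect differed from that in CD8 T cell-like cells changed in number with the processing, and the cause was not tested. As reported they numbered 14 in B, 20 in CD4 T, 3 in NK or ILC1, 2 in Treg, 23 in cDC2, 186 in classical monocyte, 45 in epithelial, 12 in mature DC, 15 in macrophage, 41 in neutrophil, 36 in non-classical monocyte and 22 in pDC cells. With doublets kept they numbered 60 in CD4 T, 1 in Treg, 65 in cDC2, 424 in classical monocyte, 19 in mature DC, 97 in neutrophil, 22 in non-classical monocyte and 114 in pDC cells. RLE size factors gave 1 in NK or ILC1, 22 in epithelial and 19 in mature DC cells. With 1 library left out they ran from 0 to 221 in B, from 0 to 51 in CD4 T, from 0 to 92 in NK or ILC1, from 1 to 79 in Treg, from 3 to 171 in cDC2, from 1 to 345 in classical monocyte, from 13 to 262 in epithelial, from 3 to 39 in mature DC, from 0 to 300 in macrophage, from 0 to 115 in neutrophil, from 3 to 45 in non-classical monocyte and from 0 to 144 in pDC cells. For the type I interferon list, the median log2 difference from CD8 T cell-like cells with doublets kept was 0.0466 in Treg, 0.59 in cDC2 and 0.0786 in pDC cells, and 0 classes passed in fry against 2 in the reported fit. Leaving out 1 library gave 0 or 1 classes, with median log2 differences from -0.10 to 0.18 in CD4 T, from -0.21 to 0.31 in Treg, from 0.30 to 0.49 in cDC2, from -0.80 to 0.0567 in epithelial and from 0.30 to 0.41 in pDC cells.

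Pairs of a list and a class past adjusted p 0.05 in the camera test with a preset correlation numbered 108, 102 and 85 for IFNa against Control, the combination against Control and the combination against IFNa. The fry test and camera with an estimated correlation gave 0 in each, and the cause was not tested. With doublets kept, 4 pairs passed for the combination against Control; with 1 library left out, 0 to 3 passed for IFNa against Control and 0 to 1 in each of the other comparisons. List medians for IFNa against Control that changed sign with classes from marker scores were -0.14 for the type 1 regulatory T cell list in CD4 T, -0.48 for the proliferation list in CD8 T, -0.0109 for the regulatory T cell list in Treg and 0.13 for the MHC class II presentation list in classical monocyte cells. Others were -2.05 for the erythroid transcripts list in classical monocyte, -0.0129 for the colorectal cancer epithelial transcripts list in epithelial and -0.77 for the Kupffer cell identity list in macrophage cells. The same classes gave -0.0131 for the type I interferon response list in CD8 T cells for the combination against IFNa. Keeping doublets gave -0.0413 for the cytotoxic effector list in CD8 T and -2.04 for the erythroid transcripts list in classical monocyte cells for IFNa against Control. Leaving out 1 library, log2 medians for IFNa against Control ran from -0.34 to 1.93 for the T cell exhaustion list in CD8 T, from -0.65 to 0.38 for the cytotoxic effector list in CD8 T, from -1.37 to 0.30 for the naive or stem-like T cell list in CD8 T, from -0.00713 to 0.30 for the cytotoxic effector list in NK or ILC1 and from -0.0749 to 0.0979 for the regulatory T cell list in Treg cells. They ran from -0.56 to 0.31 for the MHC class II presentation list in classical monocyte, from -1.19 to 3.38 for the erythroid transcripts list in classical monocyte, from -0.0723 to 1.48 for the interferon-gamma-inducible GTPases and chemokines list in epithelial and from -0.19 to 2.09 for the Kupffer cell identity list in macrophage cells. Single genes that changed sign for IFNa against Control ran from -0.34 to 1.10 for Pdcd1 in CD8 T, from -0.15 to 1.91 for Tox in CD8 T, from -0.10 to 0.47 for Arg1 in classical monocyte and from -0.40 to 0.65 for H2-Ab1 in classical monocyte cells. With classes from marker scores, the Cd3e log2 fold change in macrophage-like cells, the combination against IFNa, was -1.23; the cause of these changes of sign was not tested.

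Cell class shares, tested in edgeR as log2 ratios, lost their place below adjusted p 0.05 in the following settings, where the cause was not tested. With immune cells as denominator the values were -1.51 in classical monocyte for the combination against Control, and -2.10 in basophil or mast, -1.66 in mature DC and 3.23 in plasma for the combination against IFNa. Over named cells other than T and NK the values were -2.64 in basophil or mast, -0.54 in classical monocyte, -2.67 in erythroid and -1.72 in macrophage for the combination against Control, and -1.32 in basophil or mast, -2.63 in erythroid and -0.86 in mature DC for the combination against IFNa. TMM over classes gave -0.65 in classical monocyte for the combination against Control, and -1.41 in basophil or mast and -0.94 in mature DC for the combination against IFNa. Keeping doublets gave 3.22 in plasma for the combination against Control, and 1.56 in CD8 T, -1.69 in basophil or mast, -1.01 in mature DC, -3.02 in neutrophil and 3.04 in plasma for the combination against IFNa. The stricter cell filter gave -2.03 in classical monocyte, -1.48 in erythroid, -2.79 in macrophage and 3.28 in plasma for the combination against Control, and 1.52 in CD8 T, -2.10 in mature DC and 2.89 in plasma for the combination against IFNa. Doubling the cluster resolution gave -2.64 in macrophage and 3.34 in plasma for the combination against Control, and 1.57 in CD8 T, -2.10 in mature DC and 2.83 in plasma for the combination against IFNa. Interferon and MHC genes kept in clustering gave 3.15 in plasma for the combination against Control, and 1.54 in CD8 T, -2.07 in mature DC and 2.79 in plasma for the combination against IFNa. Marker scores gave -0.92 in basophil or mast for the combination against IFNa. Marker scores also turned the sign, to 1.39 in erythroid for the combination against Control (edgeR adjusted p = 0.0329), and 1.30 in erythroid (edgeR adjusted p = 0.0398) and 0.26 in mature DC for the combination against IFNa, so that erythroid-like cells passed the other way, while neutrophil-like cells, IFNa against Control, passed at -1.91. With 1 library left out, log2 ratios for the combination against Control ran from 1.90 to 2.27 in CD8 T, from -2.09 to -1.87 in classical monocyte, from -4.13 to -3.83 in erythroid and from 1.63 to 4.99 in plasma. Against IFNa they ran from 1.22 to 1.95 in CD8 T and from -2.67 to -2.32 in basophil or mast. Others were -3.90 to -3.69 in erythroid, -2.23 to -1.90 in mature DC and 2.01 to 4.72 in plasma. Classes past 0.05 for the combination against IFNa numbered 8 as reported, 4 over immune cells or over named cells other than T and NK, 3 with doublets kept and 3 to 7 with 1 library left out. Against Control the combination had 8 as reported, 3 over named cells other than T and NK, 5 with the stricter filter and 5 to 8 with 1 library left out, and IFNa had 0 as reported in edgeR and 1 with marker scores.

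Among T cells of no finer class, the percent of expanded receptors was 0 in Control 11 over cells with exactly 1 TRA and 1 TRB, before and after thinning, and 7.54% in IFNa 23 and 16.6% in the combination library with doublets kept. Over TRB alone, 62.9% of the receptors of the combination library were expanded; the cause was not tested.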

Other observations

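The values given here were all chosen after the data were seen, and none was tested. Naive-like subclusters, defined by Ccr7 in at least 50% of cells, held 15.6% of the CD8 T cell-like cells of the combination liver and 21.4% in IFNa 23, against 66.8% in IFNa 18 and 63.9% and 32.3% in Control 11 and 25. In CD4 T cell-like cells the shares of the same livers in that sequence were 13.8%, 17.3%, 52.5%, 69.7% and 42.9%. A CD8 subcluster led by Ccl3, Prf1, Havcr2 and Lag3 held 27.7% of CD8 T cell-like cells in the combination and 39.1% in IFNa 23, against 7.38% in IFNa 18 and 9.02% and 6.45% in Control. Its largest clonotype took 87 of 145 paired barcodes in IFNa 23 and 91 of 377 in the combination, and 15 of 21 in Control 11, 2 of 2 in Control 25 and 9 of 20 in IFNa 18.

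A CD8 subcluster of 98 cells carried Foxp3, the regulatory T cell transcription factor. Foxp3 UMIs were found in 87.8% of its cells, against 0.83% of the other CD8 T cell-like cells and 0.43% of B-like cells, at median depths of 7445.5, 6610 and 4117.5 UMIs. Of the 98 cells 67 came from the combination, 27 from IFNa 23, 3 and 1 from Control and 0 from IFNa 18. In the combination 58 paired barcodes fell into 28 clonotypes, the largest of 8, and in IFNa 23 19 barcodes fell into 13. Across livers 1 paired clonotype was shared, between IFNa 23 and the combination, and the other 9 pairs of livers shared 0.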
